A study of Mus musculus with 2 samples.

How the data were processed

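Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against H3K4me3, the trimethylated lysine of histone H3 found at promoters, was carried out on mouse hindbrain at embryonic day 16.5. Per the labels, the embryos were of strain B6NCrl, male and female hindbrains were pooled, and the series held 1 group with 2 biological replicates. The hindbrains of 37 embryos were pooled for replicate 2, and the number behind replicate 1 was not given in the sources used here. The labels call the replicates biological, and the spread between them includes both the animals and the handling of the tissue. The series has no second tissue, stage or treatment, so no test between conditions was possible.

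The authors deposited 4 lists of peaks on the mouse genome build mm10, per the text files deposited with the samples. There was 1 list for each replicate alone, 1 for both replicates pooled and 1 named replicated. Every peak of the replicated list was found as a peak of the pooled list. Of its 25150 peaks, 21965 (87.3%) overlapped a peak in both replicate lists and 3185 did not, so an overlap of 1 bp with both replicate lists was not the rule behind it. The peak caller, its version, its threshold and any control treatment were not given in the sources used here. The replicate 1 list was made from its alignment and 2 further files, and the replicate 2 list from its alignment and 1 further file. The roles of these further files were not stated, and a difference in them could change how many weak regions were listed.

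Each peak came with a signal value, a score whose scaling the authors did not state in the deposited text, and it was used only to rank peaks within 1 list. The deposited lists also gave a −log10 q-value per peak, which reached down to 0.19 in the replicated list. The lists therefore held weak regions, and 21053 of the 25150 replicated peaks had a −log10 q of at least 5. Read counts were not used here, so the depth of each library is unknown and no counting interval was given for the values of single peaks. A less deeply sequenced library can miss weak peaks and give narrower ones.

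Transcript starts were taken from GENCODE release M21 and sequence from GRCm38 patch 6, the same coordinates as mm10, and no peak ran past the end of a reference chromosome. A protein-coding gene was called marked where a peak lay within 1 kb of any of its annotated transcript starts. Peaks were joined over gaps of up to 1 kb into domains, and the width of a gene was that of its widest domain reaching within 1 kb of a start. Neighbouring genes can share a domain and then have the same width. A promoter was called CpG-rich where the observed to expected CpG ratio was at least 0.6 and GC content at least 50% within 500 bp of the gene's 5' end. Distal peaks lay over 5 kb from every annotated transcript start. Peaks outside the main chromosomes were left out of counts by gene and by class.

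Overlap between replicates needed at least 1 bp, and the chance level came from placing the peaks of replicate 2 at random on their own chromosomes 100 times with bedtools 2.31.1. Marking of 23 gene lists was compared with all other protein-coding genes by Fisher's exact test, two-sided. Median domain width was compared with all other marked genes by a permutation test with 100000 resamples, two-sided, for the 18 lists with at least 5 marked members. The smallest p these permutations can give is 2e-05. Benjamini-Hochberg adjustment was made over the 23 lists for marking and over the 18 lists for width. Lists compared with each other were tested in the same way without adjustment. Genes are the units of these tests, so the p-values describe differences between sets of genes in these tissue pools and not variation between animals. Values of single genes are given as the mean of the replicate lists with the SD (n = 2), or as the width in the replicated list where stated.

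The gene lists, tests and definitions, and most alternatives, were fixed before the data were examined. The genes named were the 25 with the widest promoter domains in the replicated list that were marked in each replicate list, with 1 gene per domain, all Hox genes, and the 5 distal peaks with the highest signal value. In each list the 2 marked members with the widest domains and the first 2 unmarked members in list order were also named. Other genes named below were chosen after their values were seen. The alternatives were the pooled list, each replicate alone, a −log10 q of at least 5, distances of 0 bp and 2.5 kb, the gene's 5' end alone, no joining or joining over 3 kb, CpG-rich promoters alone, and permutation within 5 equal classes of CpG number within 2 kb. A further 2 were added after the data were seen, namely 1 gene per domain and the base pairs under peaks within 10 kb of the start.

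The scripts were tested on simulated data before use. All of 2000 simulated marked genes were recovered (100%), and 5.0% of unchanged lists of 20 real genes gave p under 0.05 in the width test. Lists of 20 widened 1.5-fold passed that level in 93.0% of 100 draws, and lists widened 2-fold in 100%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.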

Results

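H3K4me3 was mapped in the hindbrain of mouse embryos at day 16.5 of gestation, in 2 biological replicates of 1 group. The hindbrain gives rise to the cerebellum, pons and medulla. The replicate 1 list held 29356 peaks covering 37.6 Mb, and the replicate 2 list held 24863 peaks covering 32.9 Mb. The replicated list, on which the values below rest unless stated, held 25150 peaks with a median width of 1262 bp. The depth of the libraries is unknown.

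The first comparison asked how far the replicates shared their marked regions. Strong H3K4me3 regions were shared by the pools of tissue, and the regions listed in only 1 of them were narrow and weak. Of the replicate 1 peaks, 22974 (78.3%) overlapped a replicate 2 peak, against 2.62% for randomly placed peaks. Of the replicate 2 peaks, 24093 (96.9%) overlapped a replicate 1 peak, against 2.78% at random. The promoters of 14352 protein-coding genes were marked in both replicates, 213 in replicate 1 alone and 35 in replicate 2 alone.

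Every peak with a signal value at or above the median of its list overlapped a peak of the other replicate (100% in both directions). The 6382 unshared peaks of replicate 1 had a median width of 251 bp, and the 770 unshared peaks of replicate 2 had a median width of 220 bp. Domain width at promoters was ranked alike in the replicates, with a Spearman correlation of 0.941 across the 14352 genes, which are not independent replicates. Widths lay within 1.5 times of each other for 94.2% of these genes. Replicate 1 was wider by at least that factor at 785 genes and replicate 2 at 45 genes, and the median ratio of replicate 1 to replicate 2 was 1.08.

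**Figure D1:**
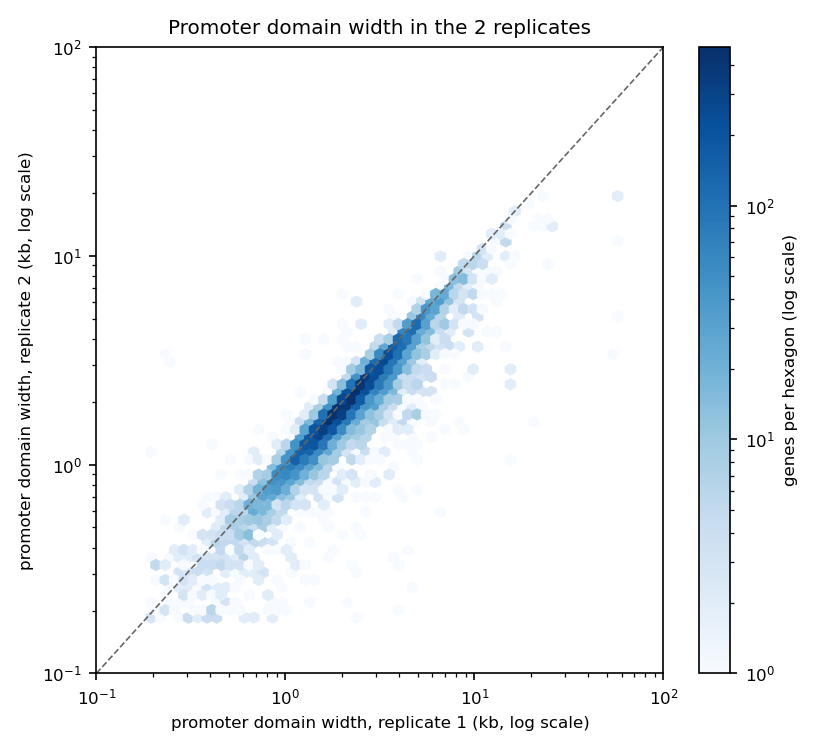
Width of the widest promoter domain of each protein-coding gene marked in both replicates, in kb on log scales, with replicate 1 on the horizontal and replicate 2 on the vertical axis; colour gives the number of genes per hexagon and the dashed line marks equal widths. Most of the 14352 genes lie near the line, and more of the outlying genes are wider in replicate 1 (785) than in replicate 2 (45).

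The second comparison asked where the mark lay. H3K4me3 was found mainly at promoters, and 14503 of 21911 protein-coding genes (66.2%) were marked. The number of marked genes was 14476 ± 126 (SD, n = 2) over the replicate lists. Of the peaks on the main chromosomes, 68.0% were at promoters, 18.2% in gene bodies and 13.9% between genes, and the promoter peaks held 86.6% of the base pairs under peaks. The promoter share of peaks was 62.5% in replicate 1 and 70.2% in replicate 2, and it rose to 75.6% among peaks with a −log10 q of at least 5. Of the distal peaks, of which there were 4299 with a median width of 504 bp, 3292 overlapped peaks in both replicate lists.

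The distal peaks with the highest signal values lay far from coding genes in most cases. The strongest was at chromosome 9, 32031511 to 32034394, between genes and 83.2 kb from the nearest coding start, that of Arhgap32. Another lay at chromosome 8, 69715929 to 69717019, between genes and 5.75 kb from a start of Zfp869. The next lay at chromosome 12, 8640223 to 8641761, between genes and 33.1 kb from a start of Pum2. A peak at chromosome 15, 85669655 to 85674979, lay in an intron of the noncoding gene Lncppara and 62.7 kb from a start of Ppara. The last of the 5 lay at chromosome 18, 23309370 to 23311821, between genes and 104.5 kb from a start of Dtna. All were present in both replicates.

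The third comparison asked how marking related to promoter sequence. Nearly all CpG-rich promoters carried the mark, and the other promoters carried it less often. Of 9723 CpG-rich promoters 9622 (99.0%) were marked, and of 12188 other promoters 4881 (40.0%) were marked (Fisher's exact test, odds ratio 143, p below 1e-300). The shares were 99.0% and 40.5% in replicate 1 and 98.9% and 39.2% in replicate 2. Here the class was read at the gene's 5' end and the mark at any transcript start. With both read at the 5' end, 33.5% of promoters outside the class were marked, forebrain factors left out. The marked domains had a median width of 2243 bp at CpG-rich promoters and 1660 bp at the others. The 101 unmarked CpG-rich promoters included those of the meiotic genes Sycp1 and Sycp3, of the germ cell helicase Ddx4, and of Hoxa11, Hoxc9, Hoxc11, Hoxc12 and Hoxd10. Of these 101 promoters, 45 had a near-identical copy at another gene, where the placing of reads, and so the absence of a peak, is uncertain.

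The fourth comparison asked which promoters carried the widest domains. The 25 widest included those of Hox, Meis, Zic, Lhx and Pou3f transcription factor genes. The domain assigned to Hoxb4 spanned 43.4 kb in the replicated list (chromosome 11, 96291621 to 96335014) and also took in Hoxb3, Hoxb5 and Hoxb6. For Hoxb4 the width was 57.3 kb in replicate 1 and 3.44 kb in replicate 2, so no stable width can be given. Nr2f2, a nuclear receptor gene, had 25.2 kb in the replicated list (chromosome 7, 70345633 to 70370813) and 20.4 kb ± 7.38 (SD, n = 2) over the replicates. Ebf3, a factor of neuronal differentiation, had 23.1 kb in the replicated list (chromosome 7, 137300184 to 137323290) and 18.7 kb ± 6.23 over the replicates.

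The homeobox gene Meis2 had a domain of 21 kb ± 2.36 over the replicates, and its domain in the replicated list lay at chromosome 2, 116052185 to 116073232. The nuclear factor gene Nfib had 19.8 kb in the replicated list (chromosome 4, 82493994 to 82513780) and 18.4 kb ± 1.08 over the replicates. Zic1 and Zic4, zinc finger genes of the cerebellum, shared a domain of 18.5 kb in the replicated list (chromosome 9, 91357337 to 91375858), wider than in either replicate (12.8 kb ± 1.93). The LIM homeobox genes Lhx1 and Lhx5 had domains of 18.3 kb ± 3.94 and 16.8 kb ± 0.342. Pax6, expressed in progenitors and cerebellar granule cells, had a domain of 16.9 kb ± 0.436, and Pou3f2, a POU factor, one of 15.2 kb ± 0.104. Zic2 reached 14.6 kb ± 0.0375, Meis1 14.5 kb ± 0.251 and Nr2f1 13.5 kb ± 2.22. Hoxa2, in a domain shared with Hoxa1, reached 19.7 kb ± 7.53, and Pou3f3 17.7 kb ± 5.47.

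The remaining widest domains were at Mn1, Setd1b, Myt1l, Tnrc18, Irx5, Kdm6b, Tshz1, Bahcc1, Bcl11a and Pcdh10. Among these, Setd1b encodes a histone H3 lysine methyltransferase and had 13.8 kb ± 0.165, and Kdm6b encodes a histone H3 lysine demethylase and had 12.5 kb ± 0.213. Myt1l, a factor of neurons, had 13.3 kb ± 0.845, and the protocadherin gene Pcdh10 had 11.0 kb ± 0.871. A width over 4 kb was found at 1360 genes and one over 10 kb at 59.

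The fifth comparison asked which cell types and programs of the tissue were marked. Pan-neuronal, progenitor, cell cycle and housekeeping genes were all marked, and those of liver, blood, microglia, germ cells and chemosensory receptors were largely unmarked. Of the 23 lists, 9 were marked more often than other genes, 6 less often, and 8 did not pass the test. In width, 7 of 18 lists were wider, 4 narrower, and 7 did not pass. Among CpG-rich promoters alone, of which 99.0% were marked, none of the 9 higher calls passed the test. The liver, erythroid, microglial, muscle and chemosensory lists, all called lower, held few CpG-rich promoters (0 of 16, 0 of 13, 1 of 15, 3 of 15 and 1 of 1499).

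Neuronal genes were marked with wide domains. All 24 pan-neuronal genes were marked (Fisher's exact test, adjusted p = 0.000309), with a median width of 4123 bp against 2081 bp for other marked genes (permutation test, adjusted p = 9.0e-05). The RNA-binding protein genes Elavl4 and Celf4 had the widest domains of the list, 10.5 kb ± 1.39 and 8.33 kb ± 1.08 (SD, n = 2). Of 20 genes of excitatory and inhibitory transmission, 19 were marked (Fisher's exact test, adjusted p = 0.00725), and Slc17a8, a vesicular glutamate transporter gene, was not. With the gene's 5' end alone this call ended (85.0%, adjusted p = 0.0637 by Fisher's exact test, with a range of 0.000964 to 1.0 over all alternatives). Their median width was 3369 bp (permutation test, adjusted p = 0.00144). Gad1, which encodes a GABA-synthesising enzyme, had 9.57 kb ± 2.34 and the GABA and glycine vesicular transporter gene Slc32a1 had 11.7 kb ± 0.872.

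Progenitor genes were also marked with wide domains. All 20 neural progenitor genes were marked (Fisher's exact test, adjusted p = 0.00105), with a median width of 4734.5 bp (permutation test, adjusted p = 9.0e-05). Pax6 and Sox2 led this list, and Sox2, a factor of neural stem cells, had 9.75 kb ± 1.01. All 20 cell cycle genes were marked (Fisher's exact test, adjusted p = 0.00105), and their median width of 2297.5 bp did not pass the permutation test against other marked genes (adjusted p = 0.443). The proliferation marker gene Mki67 had 3.10 kb ± 0.658 and the replication helicase gene Mcm7 had 3.27 kb ± 0.0311. All 20 housekeeping genes were marked (Fisher's exact test, adjusted p = 0.00105), with a median width of 2989.5 bp (permutation test, adjusted p = 0.00949). Ywhaz and Tubb5 had the widest domains among them, 5.03 kb ± 1.44 and 4.92 kb ± 0.382. Without joining of peaks the width call for housekeeping genes ended (adjusted p = 0.0515 by the permutation test, the highest over all alternatives, the lowest being 0.00312).

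Glial lists were divided between marked and unmarked members and did not pass either test. Of 18 oligodendrocyte lineage genes 12 were marked (Fisher's exact test, adjusted p = 1.0). The precursor genes Olig2 and Pdgfra had 7.69 kb ± 0.682 and 6.21 kb ± 0.416, and the myelin genes Plp1 and Mog were unmarked. Of 14 astrocyte genes 12 were marked (Fisher's exact test, adjusted p = 0.206). The glutamate transporter gene Slc1a2 and the receptor gene Fgfr3 had 5.08 kb ± 1.20 and 4.46 kb ± 1.35, and Gfap and S100b, genes of mature astrocytes, were unmarked. Median widths were 2404 bp and 2908.5 bp for the lists (permutation tests, adjusted p = 0.433 and 0.0551). The astrocyte width passed the permutation test at a distance of 0 bp (adjusted p = 0.0436) and with the gene's 5' end alone (adjusted p = 0.0318, the lowest over all alternatives, the highest being 0.742).

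Microglial genes were marked in 1 of 15 cases (Fisher's exact test, adjusted p = 1.49e-05), the lysosomal gene Hexb, and Aif1 and Cx3cr1 were unmarked. Without replicate 2 the count was 3 of 15 (20.0%), still below other genes (Fisher's exact test, adjusted p = 0.000992, with a range of 1.34e-05 to 1.0 over all alternatives). Of 14 endothelial genes 13 were marked, 13 in replicate 1 and 10 in replicate 2 (Fisher's exact test, adjusted p = 0.0638). The receptor gene Kdr had 3.47 kb ± 0.689 and Fli1 had 3.47 kb ± 0.446, and the receptor gene Tie1 was unmarked. Of 15 meningeal and mural genes 12 were marked (Fisher's exact test, adjusted p = 0.5), with Foxc1 and Pdgfrb the widest, and Rgs5 and Lum unmarked. Median widths of 1778 bp for endothelial and 2208 bp for meningeal and mural genes did not pass the permutation test (adjusted p = 0.402 and 0.710), and the endothelial genes passed it as narrower with the gene's 5' end alone (adjusted p = 0.0328, the lowest over all alternatives, the highest being 0.920). Of 12 choroid plexus genes 7 were marked (Fisher's exact test, adjusted p = 0.637), with Msx1 and Kl the widest, and Ttr and Aqp1, which serve transport in that epithelium, unmarked. In each replicate list 6 were marked, and Slc4a5, with 240 bp in the replicated list, was marked in neither. The marked choroid plexus genes had narrow domains with a median of 1266 bp (permutation test, adjusted p = 0.0352), a call that ended in each replicate alone (adjusted p = 0.0939 without replicate 1 and 0.135 without replicate 2, with a range of 0.0287 to 0.246 over all alternatives).

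Genes of cholinergic and monoaminergic neurons were tested as separate lists. All 12 cholinergic motor neuron genes were marked (Fisher's exact test, adjusted p = 0.0177), with Nkx6-1 and Ache the widest. Of 13 monoaminergic genes 9 were marked (Fisher's exact test, adjusted p = 1.0). Gata3 and Gata2, factors of serotonergic and other neurons, had 4.15 kb ± 1.66 and 4.47 kb ± 0.376, and the enzyme genes Tph2 and Ddc were unmarked. The widths of the lists did not pass the test (permutation tests, adjusted p = 0.433 and 0.44). Narrower widths passed the permutation test for monoaminergic genes with the gene's 5' end alone (adjusted p = 0.00461) and for cholinergic genes without joining (adjusted p = 0.0185), the lowest values over all alternatives of each list. The cholinergic call on marking was lost at a distance of 0 bp (91.7%, Fisher's exact test, adjusted p = 0.103) and with the gene's 5' end alone (75%, adjusted p = 0.707), and its adjusted p ranged from 0.0165 to 1.0 over all alternatives.

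Genes of other tissues were marked less often than the remaining genes. Outside the CpG-rich class, where 40.0% of promoters were marked, the shares were 1 of 16 for liver and 3 of 12 for muscle genes. In tests chosen after the result was seen, only the liver share passed (Fisher's exact test, p = 0.00418 for liver and 0.383 for muscle). Erythroid genes, with 3 of 13 marked, were not tested in this way. Of 16 liver genes 1 was marked (Fisher's exact test, adjusted p = 9.46e-06), Trf, which is also expressed in brain glia, and Alb and Afp were unmarked. Of 13 erythroid genes 3 were marked (adjusted p = 0.00389 by Fisher's exact test), Epor and Klf1 among them, and the globin genes Hbb-bs and Hbb-bt were unmarked. Of 15 muscle genes 5 were marked (adjusted p = 0.0177 by Fisher's exact test), with Mylpf and Myod1 the widest and Myf5 and Myog unmarked. The muscle call ended at a distance of 2.5 kb (46.7%, Fisher's exact test, adjusted p = 0.138, with a range of 2.93e-05 to 0.216 over all alternatives), where the liver share was 18.8%, and at 0 bp the shares were 6.67% for muscle and 7.69% for erythroid genes. Of 20 germline and pluripotency genes 4 were marked (adjusted p = 0.000117 by Fisher's exact test), Brdt and Dazl with the widest domains, and Ddx4 and Mael unmarked. Of 1499 chemosensory receptor genes 4 were marked (0.267%, adjusted p below 1e-300 by Fisher's exact test), with Vmn1r4 and Olfr94 the widest.

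**Figure D2:**
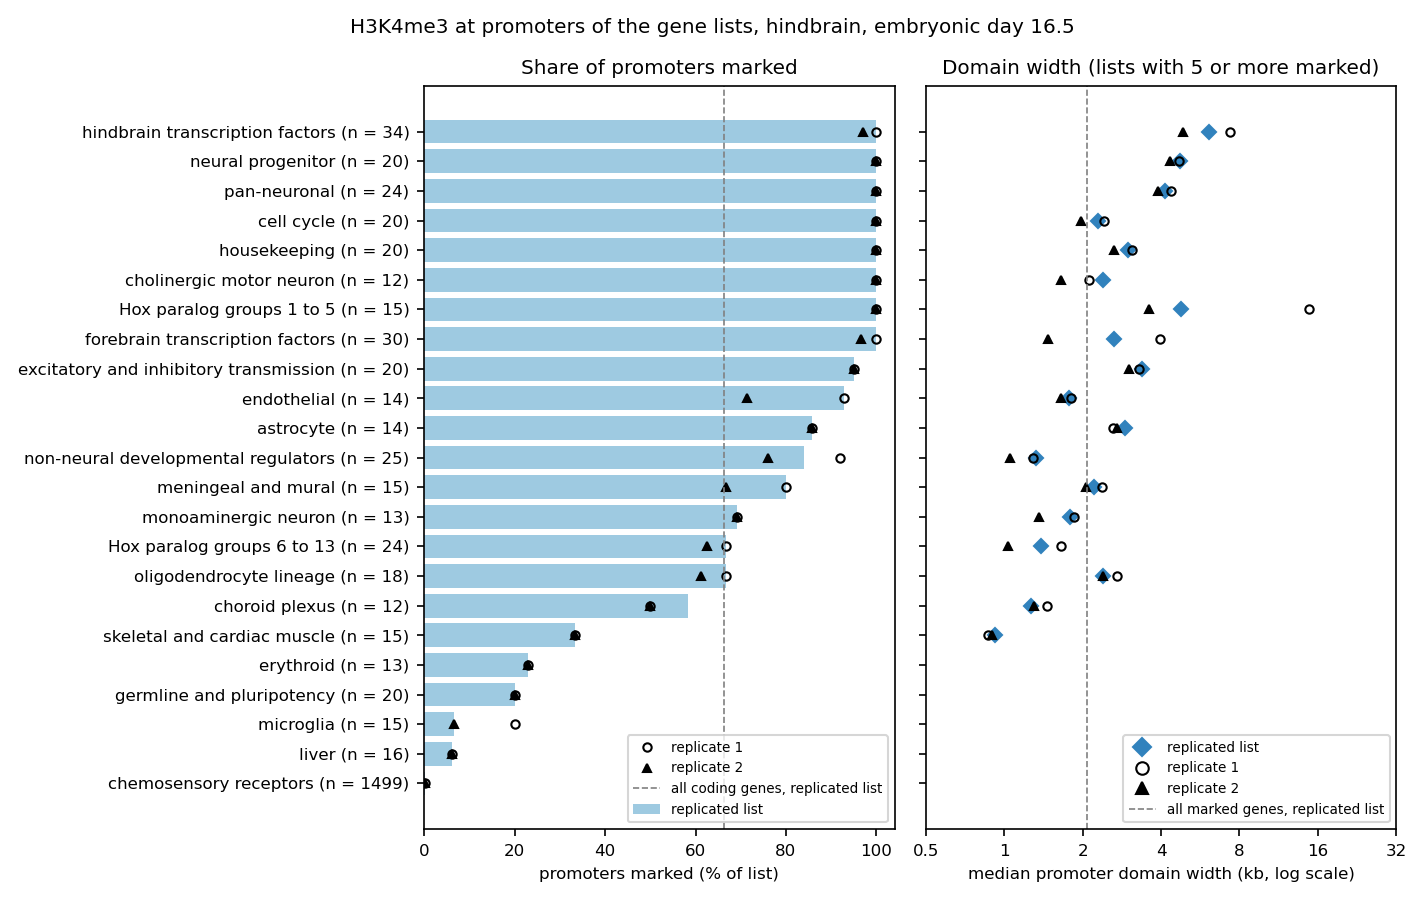
Share of promoters marked in each gene list in percent (left) and median promoter domain width of its marked members in kb on a log scale (right), with bars or diamonds for the replicated list, open circles for replicate 1 and triangles for replicate 2; dashed lines give the values of all protein-coding genes (66.2%) and of all marked genes (2083 bp). Hindbrain factors, at 6100.5 bp in the replicated list, lie to the right of most lists, and the median width of anterior Hox genes is 14763 bp in replicate 1 and 3586 bp in replicate 2.

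The sixth comparison asked how the mark differed between transcription factors of the hindbrain and of the forebrain. Both kinds of factor were marked without exception in the replicated list, and the domains of hindbrain factors were wider. In that list all 34 hindbrain and all 30 forebrain factors were marked (adjusted p = 9.46e-06 and 2.80e-05 against other genes by Fisher's exact test). In replicate 2 the counts were 33 of 34 and 29 of 30, with Phox2b and Rax unmarked. At a distance of 0 bp 32 of 34 hindbrain factors were marked, and the forebrain call ended (83.3%, adjusted p = 0.0569 by Fisher's exact test, with a range of 2.92e-05 to 1.0 over all alternatives). The median width was 6100.5 bp for hindbrain factors and 2627 bp for forebrain factors, a difference of 3473.5 bp (permutation test, p = 6.0e-05). The difference was 3386 bp in replicate 1 and 3372 bp in replicate 2. The series holds no forebrain sample, so how far the factors of each list are limited to its region was not tested. Counting only the gene's 5' end, all hindbrain factors and 86.7% of forebrain factors were marked (Fisher's exact test, p = 0.0431).

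Meis2 and Nfib had the widest domains among hindbrain factors. Among forebrain factors these were at Bcl11b, a zinc finger gene, with 8.26 kb ± 2.05 (SD, n = 2), and Lhx2, a LIM homeobox gene, with 8.99 kb in replicate 1 and 2.68 kb in replicate 2. Hindbrain factors were wider than other marked genes (permutation test, adjusted p = 9.0e-05). Forebrain factors passed the same test in the replicated list (adjusted p = 0.0352), but the direction turned in replicate 2 alone, where the difference of their median from that of other genes was -456.5 bp (permutation test, adjusted p = 0.0177, with a range of 7.20e-05 to 0.909 over all alternatives). Their median was 3974.5 bp in replicate 1 and 1471 bp in replicate 2, so no direction can be given for the list.

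Developmental regulators of non-neural tissues were narrower than other genes where they were marked. Of 25 such genes 21 were marked (84.0%, Fisher's exact test, adjusted p = 0.119), and the marking passed the test with replicate 1 alone (92.0%, Fisher's exact test, adjusted p = 0.00831, the lowest over all alternatives). Their median width was 1322 bp (permutation test, adjusted p = 0.00115), a call that ended when base pairs under peaks within 10 kb were counted (adjusted p = 0.0799, the highest over all alternatives, the lowest being 6.0e-05). Foxf2 and Gata6 had the widest domains, 5.42 kb ± 0.729 and 3.40 kb ± 0.389. Pdx1, a pancreatic factor, and Hnf1b were unmarked in the replicated list and in replicate 2, but marked in replicate 1 (195 bp and 762 bp). The marked muscle genes were narrow as well, with a median of 925 bp (permutation test, adjusted p = 0.0108), a call that ended with joining over 3 kb (adjusted p = 0.441, the highest over all alternatives, the lowest being 0.000315).

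The seventh comparison asked how the mark was placed along the Hox clusters, whose genes specify position along the body axis and whose anterior members are active in the hindbrain. All 15 genes of paralog groups 1 to 5 were marked, against 16 of 24 (66.7%) of groups 6 to 13 (Fisher's exact test, p = 0.0146). The genes unmarked in the replicated list were Hoxa10, Hoxa11, Hoxb13, Hoxc9, Hoxc11, Hoxc12, Hoxd10 and Hoxd12. Of these, Hoxa10 was marked in replicate 1 alone (836 bp) and Hoxb13 in replicate 2 alone (228 bp). Neighbouring Hox genes can share a domain and are not independent.

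The median width was 4785 bp in groups 1 to 5 and 1382 bp in groups 6 to 13, a difference of 3403 bp that did not pass the permutation test (p = 0.0883). The difference was 13105 bp in replicate 1 (p = 0.0276 by the permutation test) and 2550 bp in replicate 2 (p = 0.0108 by the permutation test), and its size was thus set by the replicate used. Against all other marked genes, groups 1 to 5 were wider (permutation test, adjusted p = 9.0e-05) and groups 6 to 13 narrower (adjusted p = 0.00777), the second of which was lost with replicate 1 alone (adjusted p = 0.132, with a range of 6.0e-05 to 0.426 over all alternatives). Counted as base pairs under peaks within 10 kb, the direction for groups 6 to 13 turned, with a difference of 392.5 bp. The difference for groups 1 to 5 was 1659 bp in replicate 2 and 12643 bp in replicate 1. Hoxb6 and Hoxa6 had the widest domains of groups 6 to 13, each in a domain shared with an anterior gene, Hoxb3 and Hoxa3.

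Peaks covered 41.1% of the Hoxa cluster in replicate 1 and 28.0% in replicate 2, and 36.3% and 24.5% of the Hoxb cluster. Coverage was 28.0% and 21.6% at Hoxd and 13.3% and 8.59% at Hoxc. In every cluster the covered base pairs were higher in replicate 1. The shares were taken over windows that ran past the outermost genes of each cluster. These windows differed in length, with 184 kb at Hoxb and 115 kb at Hoxa. In base pairs Hoxb was covered more than Hoxa, with 66.8 against 47.3 kb in replicate 1 and 45.1 against 32.3 kb in replicate 2.

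**Figure D3:**
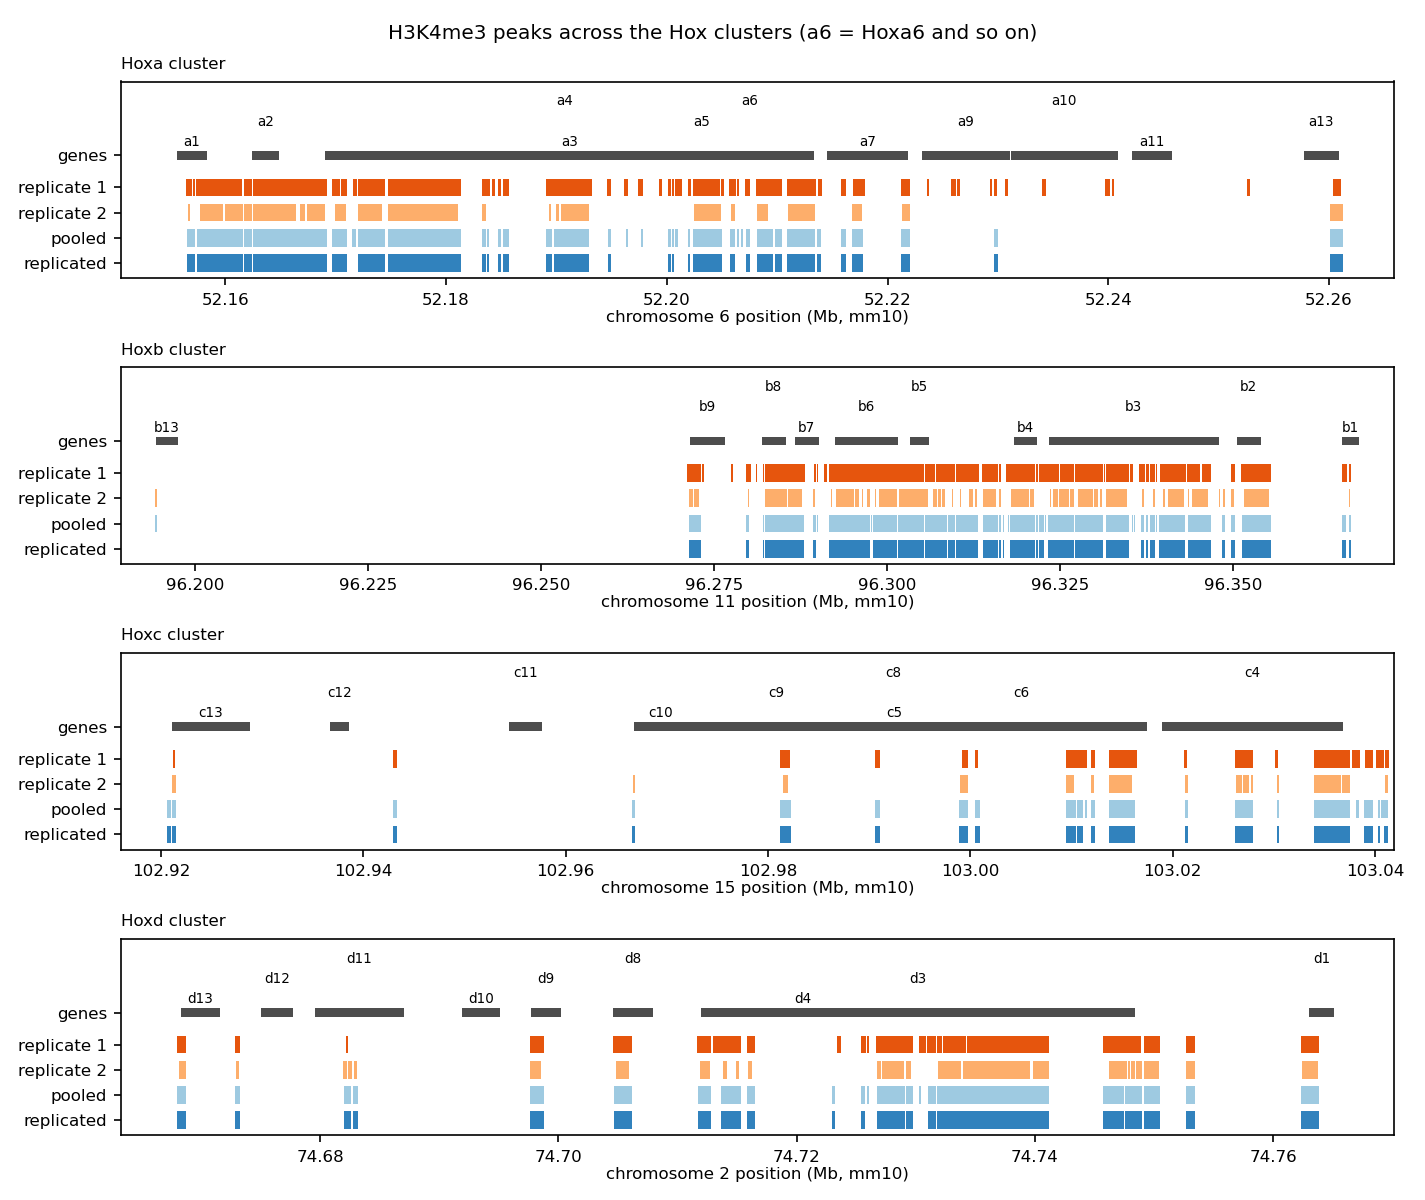
Peaks of the 4 lists across the Hoxa, Hoxb, Hoxc and Hoxd clusters, with position in Mb on mm10 on the horizontal axis, a row of coloured bars for each list and grey bars for annotated genes (a6 stands for Hoxa6). Peaks lie over genes of both the lower and the higher groups, and they cover 36.3% of the Hoxb cluster in replicate 1 and 24.5% in replicate 2.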

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

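The tests below on marked regulators of other regions and tissues were chosen after the result was seen, and those on the replicates before.

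Both results in this paragraph lie outside the comparisons of protein-coding genes on the main chromosomes, and were picked out as signal in data that the comparisons do not use. No background was measured for either count, so they are given as values alone. The replicated list held 12 peaks on 6 scaffolds not placed in the main chromosomes, with a median width of 758.5 bp. Of 5134 lincRNA genes over 5 kb from coding starts, 476 (9.27%) were marked, with 499 in replicate 1 and 441 in replicate 2.

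Replicate 1 listed more peaks than replicate 2. Different strong regions in the pools of embryos were argued against, since 100% of the replicate 1 peaks at or above the median signal value were overlapped in replicate 2. Of the peaks listed in replicate 1 alone, 83.8% lay in the lowest quartile of its list by signal value. This is the result set in advance for more weak regions passing the calling threshold there. Of the peaks listed in replicate 2 alone, 98.4% lay in the lowest quartile of that list, so such a share does not set the longer list apart. At a −log10 q of at least 5, replicate 1 still listed more peaks (22068 against 19379). Regions below that level were thus not the whole difference. Depth and the unequal number of further files behind the lists were not tested and stay open, as do differences between the pools in weak regions.

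Regulators listed here under the forebrain and non-neural tissues were marked in this hindbrain sample. Whether members of these lists are active in hindbrain cells themselves was not tested and stays open. Class and mark were first both taken at the gene's 5' end. Outside the CpG-rich class, 9 of 12 forebrain factors were marked against 33.5% of other promoters (Fisher's exact test, p = 0.00403). Marked forebrain factors were thus not limited to that class. CpG sequence as their source stays open, since the other promoters were not matched for CpG content. They included 1498 of chemosensory receptors, of which 3 were marked at any start. The mark was also read further from the 5' end than the class. Of the non-neural regulators outside the CpG-rich class, 5 of 11 were marked (p = 0.524 by Fisher's exact test), which leaves this source open for these as well. For cells of liver in the sample, 1 of 16 liver genes outside that class was marked at any start (Fisher's exact test, p = 0.00418). Liver genes as a set were thus not marked. A small share of liver cells might give no listed peak and cannot be excluded by this test. For cells of muscle 3 of 12 genes were marked (25%, Fisher's exact test, p = 0.383), too few to decide. Forebrain tissue carried over at dissection was not tested, and cells with both H3K4me3 and a repressive mark, which was not measured here, could be a further source.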

How the results depend on the processing

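The 2 settings named as added were chosen after the data were seen, and the others before. Of 443 alternative values, 367 kept their direction and their side of the threshold or moved by less than the spread, 31 lost the call, 13 gained one, 24 turned direction and 8 moved. For those that changed, the cause was not tested unless stated. Depth is unknown and limits the weak peaks.

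The wider domains of hindbrain than forebrain factors, the higher marking of anterior than posterior Hox genes, the number of marked genes and the CpG difference held in the alternatives run for each. Neither the hindbrain and forebrain comparison nor the Hox comparison was run on CpG-rich promoters alone or on base pairs under peaks within 10 kb. With CpG-rich promoters alone, 99.0% of the background was marked, so little room for higher marking remained. There the housekeeping, cell cycle, progenitor, pan-neuronal, transmission, hindbrain, forebrain, cholinergic and anterior Hox calls ended at 100%, the muscle call ended at 66.7% of 3 genes, and values turned at 100% for microglial (1 gene), choroid plexus (3 genes) and chemosensory genes (1 gene), too few to give a direction (adjusted p = 1.0 each by Fisher's exact test). Hox groups 6 to 13 were at 66.7%, now below the background (Fisher's exact test, adjusted p = 3.18e-06, the lowest of a range up to 1.0 over all promoters).

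In marking, the gene's 5' end alone ended the calls for transmission (85.0%) and cholinergic genes (75%), turned Hox groups 6 to 13 (58.3%) and oligodendrocyte genes (61.1%), and gave a difference of 13.3 percentage points between hindbrain and forebrain factors. A distance of 0 bp ended the calls for forebrain (83.3%) and cholinergic genes (91.7%) and turned Hox groups 6 to 13 (58.3%), oligodendrocyte (55.6%), endothelial (57.1%) and non-neural regulator genes (60.0%). A distance of 2.5 kb turned oligodendrocyte genes (66.7%), ended the muscle call (46.7%) and called non-neural regulators (88.0%). A −log10 q of at least 5 turned Hox groups 6 to 13 (45.8%) and oligodendrocyte genes (61.1%). Leaving out each replicate gave 62.5 to 66.7% for Hox groups 6 to 13, 61.1 to 66.7% for oligodendrocyte genes and 76.0 to 92.0% for non-neural regulators.

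Differences in median width from other marked genes are in bp. Without joining the calls ended for housekeeping (529.5) and choroid plexus genes (-716), and the direction turned for forebrain (-648), cholinergic (-648.5) and oligodendrocyte genes (-351). A −log10 q of at least 5 turned forebrain (-45.5) and ended the calls for Hox groups 6 to 13 (-519) and choroid plexus genes (-667.5). The 5' end alone ended the calls for forebrain (435.5) and choroid plexus genes (-548) and gained calls for monoaminergic (-943), astrocyte (1075.5) and endothelial genes (-617.5). Permutation within 5 equal classes of CpG number left the differences of 545 for forebrain and -817 for choroid plexus genes but ended both calls. A distance of 0 bp ended the call for Hox groups 6 to 13 (-469.5) and gained one for astrocyte genes (1025.5). The muscle call ended with 2.5 kb (-681) and with joining over 3 kb (-462). The added base pairs within 10 kb turned cholinergic genes (-221) and Hox groups 6 to 13 (392.5) and ended the calls for muscle (-888) and non-neural regulators (-559). Leaving out either replicate turned cholinergic values (-283 to -0.5) and ended the call for choroid plexus genes (-665 to -624). The forebrain direction turned only without replicate 1 (-456.5, against 1854.5 without replicate 2). The call for Hox groups 6 to 13 ended only without replicate 2 (-462, against -892 without replicate 1).

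The width difference between anterior and posterior Hox genes passed the test with the pooled list (12614 bp), without joining (2093.5 bp) and with joining over 3 kb (16812 bp). It also passed with the added 1 gene per domain (3038.5 bp). That setting kept the anterior gene of each domain shared by the lists. Hoxb6 and Hoxa6, the posterior genes with the widest domains, were thereby left out, so this pass is no support for wider anterior domains. The difference was 2550 to 13105 bp when each replicate was left out, and p ranged from 0.00192 to 0.17 over all alternatives by the permutation test. The promoter share of peaks was 75.6% at a −log10 q of at least 5, 60.0% at 0 bp, 76.4% at 2.5 kb and 62.5 to 70.2% when each replicate was left out. With 50% reciprocal overlap 82.3% of replicate 2 peaks were shared. The correlation of widths was 0.936 without joining, 0.930 with joining over 3 kb and 0.949 at a −log10 q of at least 5. No paired analysis was possible because the series holds 1 group.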

Other observations

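The tests on CpG-rich promoters without the mark and on the families of the widest domains were chosen after the result was seen, and those on the Hoxb domain and on distal peaks before.

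Widths of some lincRNA genes are given here as values, without a test. C130071C03Rik, on chromosome 13, had 29.3 kb in the replicated list, 29.8 kb in replicate 1 and 29.0 kb in replicate 2. Among hosts of neuronal microRNAs, the width in the replicated list was 15.5 kb at Mir124-2hg, wider than in either replicate (13.4 kb and 13.1 kb), and 13.4 kb at Mir9-3hg (13.4 kb and 11.3 kb). Malat1, an abundant nuclear RNA, had 10.3 kb in the replicated list, also wider than in either replicate (9.40 kb and 9.32 kb). The 10 widest also included Gm26803, with the same width as C130071C03Rik, and Gm44946 and Gm44948, with the same width as Nr2f2 in the replicated list (25.2 kb). Gm44946 had 25.6 kb in replicate 1 and 0.79 kb in replicate 2, and Gm44948 had 25.6 kb and 15.2 kb. On chromosome Y, the promoters of Kdm5d, Eif2s3y, Uty and Ddx3y were marked in both replicates, with the labels giving pooled male and female embryos. These genes were chosen after their values were seen.

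The 101 CpG-rich promoters without the mark held 8 genes of the germline and pluripotency list (7.92%), against 2 of the 9622 marked ones (Fisher's exact test, p = 4.53e-15). This restates the low marking of that list, which had been seen before, and decides nothing about the cause. A technical candidate explanation is reads shared between near-identical copies. Promoters with at least 50% of their 50-base words found around another coding gene made up 45 of the 101 (44.6%) and 23 of the 9622 (0.239%, Fisher's exact test, p = 3.66e-77). The copies may thus account for part of these promoters. None of the 45 was a gene of the germline list, and 48 promoters were in neither set, among them those of 5 Hox genes, for which the cause was not tested. The germline and pluripotency list held 20 genes and is not a full set of such genes, so others can be among the 48.

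Homeobox, Sox, Zic, Irx, Ebf and nuclear receptor genes made up 8.50% of the widest 5% of marked genes and 1.23% of the rest, after the genes of the 25 widest domains, which prompted the test, were left out (Fisher's exact test, p = 1.78e-27). The families were taken from gene symbols. Over all marked genes the shares were 11.0% and 1.23%, and 10.3% and 1.04% with an earlier choice of symbols that also took in some of other families. Such families may carry wide domains in this tissue as a hypothesis, since it was found and tested in the same lists.

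Of the distal peaks, 9.93% lay within 1 kb of a RefSeq transcript start (95% Wilson interval 9.07 to 10.9%). After random shifts of 5 to 50 kb the mean was 7.43%. The shifted positions were not kept away from GENCODE starts as the distal peaks were. The 7.43% is therefore not a like chance level, and no excess or lack can be read from it. Starts annotated only in RefSeq would have to lie near most distal peaks to account for them, and the interval excludes that. The value lay just under the bound of 10% set in advance, and the interval spans that bound.

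Base pairs under peaks across Hoxb3 to Hoxb6 differed by a ratio of 1.5 between replicate 1 and replicate 2, with 49.6 kb and 33.0 kb covered, and the widest domain of the cluster spanned 57.3 kb and 18.8 kb. A ratio under 1.5 had been set in advance for joining of neighbouring peaks as the explanation, and the value lay at that bound with no spread known. The stretch formed 1 domain in replicate 1 and 7 in replicate 2. Covered sequence and joining thus both differed, and their shares in the difference in width cannot be told apart.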
